A study of Canis lupus familiaris with 34 samples.

How the data were processed

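Gene expression was measured in canine osteosarcoma, a malignant bone tumour of the dog, on Affymetrix Canine_2 arrays. The 34 arrays came from 31 dogs. Cell lines derived from primary tumours took 25 arrays, lines derived from metastases took 3, and snap-frozen primary tumour tissue took 6. Total RNA was extracted on columns and labelled with biotin, per the labels' protocols. Groups were taken from the source label of each sample, and breed, sex, treatment, age and survival from its other labels. Titles carried 1 of 3 prefixes, which were treated as possible batches and are called title prefix 1, 2 and 3. Title prefix 1 held 4 primary lines, title prefix 2 held 19 primary and 3 metastatic lines, and title prefix 3 held 2 primary lines and all 6 tissues.

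The values used were the deposited intensities, 1 per probe set and array, made by the authors with GCRMA per the submitters' processing notes. The version of GCRMA, its settings and any further filter are not given in the sources used here. The deposited intensity values were on a linear scale, as their range showed, so log2 was taken after a floor at 1. No probe set had a value below 1, so the floor altered none. Arrays have no read depth, and the number of arrays limits the precision of each mean. With both line arrays of dog 22 averaged, column medians were 8.11 to 8.54 in primary lines, 8.11 to 8.40 in metastatic lines and 8.31 to 8.71 in tissues.

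Of 43035 probe sets, 175 controls were left out. The platform annotation gave 29264 probe sets a single symbol and 439 several, and 13332 were not listed. Of these, 27690 matched the UU_Cfam_GSD_1.0 gene table through their gene identifier, and 0 symbols changed. A probe set was kept where log2 was over 5 on at least 3 arrays, which left 18591, of which 14059 had a single symbol. The probe set with the highest mean over all arrays stood for each gene, and 7849 genes were tested. Several kept probe sets existed for 4313 genes, and the text says where those of a named breed or metastasis gene differed.

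Both line arrays of dog 22 were averaged, which left 33 columns and 24 primary lines. For list scores within title prefix 2 this average counted as title prefix 2, although it includes an array of title prefix 3, except where stated. Lines came from separate dogs per the labels. Tests across genes used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called. For primary lines against tissues a change of at least 2-fold was also required. The 3 groups shared 1 fit. Survival was tested as log2 of the survival label in lines of dogs whose treatment label was exactly SOC, an abbreviation the labels do not spell out. The time unit of survival is not given in the sources used here. No label of death or censoring was used, so every survival value was treated as a full survival time. Sex was tested in the primary lines with a sex label, and breed between Rottweiler and Golden Retriever lines with sex as a covariate. Lists were tested with limma's camera at a preset correlation of 0.01, over the 18 lists that could be tested. Single values and correlations were tested with two-sided permutation tests of 100000 draws (20000 within title prefix 2), or exact ones by full enumeration where stated.

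Before the data were examined, 22 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were T and NK cell, B and plasma cell, monocyte and macrophage, MHC class II presentation, osteoclast, endothelial, pericyte and smooth muscle, skeletal muscle, erythroid, adipocyte, osteoblast and bone matrix, cartilage, interstitial matrix, G2/M phase, G1/S phase and replication, DNA damage checkpoint and repair, hypoxia and glycolysis, cholesterol synthesis, interferon response, immediate early, complement, and osteosarcoma genes. Lists with fewer than 3 tested members were not tested as lists. For lines against tissues the named genes were the 10 in each direction with the largest fold among called genes that changed the same way in both dogs with a line and a tissue, plus the 3 members of each list with the largest absolute fold. In the other comparisons up to 8 called genes in each direction were named, or the 3 genes with the smallest p where fewer than 3 were called. Members of the osteosarcoma list and the sex-linked genes fixed beforehand could be named anywhere. CD74, CTSK, COL1A1, COL1A2, PTH1R, DLX5 and CCNB2 lie outside that rule and were named after their values were seen. List scores were means over members of values standardised across the lines.

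Lines and tissues share an animal in 2 dogs, so the pairing comes from the labels. The deviations of line and tissue from their group means correlated at 0.157 in dog 22 and at -0.175 in dog 23. The fit with dog as a random block gave an estimated correlation of 0.129.

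The gene test was tested on simulated data of 7849 genes. For each comparison 67, 67 and 66 genes were changed by 1, 2 and 4 at once, which eases the adjusted threshold. The shares recovered are therefore too high for a comparison in which few genes differ. For primary lines against tissues it recovered 32.8% of genes changed by 1 on the log2 scale, 80.6% of those changed by 2 and 97.0% of those changed by 4. A call there also needed an estimated change of at least 2-fold, which a true change of exactly that size often misses. The 32.8% is therefore not comparable with the shares of the other comparisons, which had no fold minimum. For metastatic against primary lines the shares were 26.9%, 68.7% and 89.4%. For survival they were 64.2%, 92.5% and 100%, with the change set per SD of log2 survival rather than per doubling. For sex they were 52.2%, 83.6% and 97.0%, and for breed 35.8%, 77.6% and 92.4%. In the simulated list test the 1 shifted list of 18 was called and 0 others were. Its genes were simulated as independent, so it could not show false calls that arise from correlated list members.

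Alternatives covered the filter on dim probe sets, quantile normalization, the probe set per gene, the variance model, array weights, title prefix, sex, breed, dog, treatment label, the inter-gene correlation of the lists, and leaving out each tissue or metastatic line in turn. Alternatives without primary line 4, with dogs 22 and 23 left out of the calls that were compared with them, and with an estimated correlation within title prefix 3 were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9. Unnamed probe sets and those with several symbols were left out of the gene tests.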

Results

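The data were transcript levels in 25 line arrays from primary canine osteosarcomas, 3 lines from metastases and 6 snap-frozen primary tumours. All values below are log2 of GCRMA intensity, and differences are log2 differences, unless a fold is given. Averaging both line arrays of dog 22 left 24 primary lines, and 7849 genes were tested. Tissue arrays had slightly higher column medians than primary lines (8.56 ± 0.149 SD, n = 6, against 8.34 ± 0.124, n = 24; linear intensity, exact permutation p = 0.000754). The difference between the 3′ and 5′ probe sets of actin, which rises as RNA degrades, was also larger in tissues (2.59 ± 1.15, n = 6, against 1.42 ± 0.96, n = 24; exact permutation p = 0.0149). That of GAPDH was 3.20 in tissues and 3.09 in lines (exact permutation p = 0.404). The median correlation between line arrays was 0.872, and the pair of line arrays from dog 22 correlated at 0.911. Primary lines 5 and 9, from different dogs, correlated most closely of all pairs, at 0.976.

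The series set osteosarcoma lines against osteosarcoma tissue. Tissues had higher levels of macrophage and MHC class II transcripts, and of part of the osteoclast, endothelial, adipocyte and osteoblast transcripts. Lysozyme (LYZ), a myeloid enzyme, stood at 12.15 ± 1.13 (SD, n = 6) in tissues and 2.26 ± 0.71 (n = 24) in primary lines. With 1 of 24 lines over log2 5 the line level was near background, so the 952-fold difference is best read as a lower bound. Bone sialoprotein (IBSP), a protein of mineralised matrix, stood at 11.23 ± 3.06 in tissues and at 2.86 ± 0.61 in lines. Lines had more of the D-type cyclin CCND2 (10.37 ± 0.93 against 6.21 ± 2.45), and of the hypoxia-regulated peptide ADM (12.69 ± 1.34 against 8.86 ± 1.07). In limma, 1148 genes passed the test: 437 were higher in lines and 711 higher in tissues, and 2787 had an unadjusted p under 0.05. The median over all genes was -0.05.

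The 10 named genes higher in tissues were LYZ, MMP9, ACP5, DLA-DRA, DLA-DQA1, IBSP, LAPTM5, PECAM1, HLA-DRB1 and ADGRF5. Each was over log2 5 in 6 of 6 tissues and in at most 2 of 24 lines. The gelatinase MMP9 differed by -9.64 (SE 0.51, adjusted p = 1.5e-16) and tartrate-resistant acid phosphatase ACP5, an osteoclast enzyme, by -9.04 (SE 0.65, adjusted p = 6.3e-13). The 10 named genes higher in lines were CCND2, CDH6, F3, CA9, ADM, SEMA3C, NQO1, ABCA8, NTN4 and ASPA. CDH6, a cadherin, was higher by 4.11 (SE 1.06, adjusted p = 0.0048) and tissue factor (F3) by 4.02 (SE 0.62, adjusted p = 1.1e-05). Carbonic anhydrase CA9 was higher by 3.94 (SE 1.20, adjusted p = 0.016) and over log2 5 in 18 of 24 lines and 0 of 6 tissues. Within title prefix 3, which held 2 lines and all tissues, every named tissue gene kept its call. Of the named line genes only CDH6 (7.88, adjusted p = 0.0011) and SEMA3C (2.12, adjusted p = 0.049) did. CCND2 (4.18, adjusted p = 0.183), F3 (4.48, adjusted p = 0.100) and NQO1 (3.65, adjusted p = 0.073) kept their size there without the call, whereas CA9 was at 1.08 (adjusted p = 0.520), and CA9 also lost its call in females alone (adjusted p = 0.090). With title prefix as a covariate CCND2, F3 and NQO1 were called (adjusted p = 0.012, 0.014 and 0.019), and SEMA3C (2.12, adjusted p = 0.230), CA9, ADM, ABCA8, NTN4 and ASPA were not. With title prefix as a covariate 493 genes were called, 263 of them shared with the 1148, and within title prefix 3 alone 251 were called, 140 of them shared. Only title prefix 3 held both lines and tissues, so both fits give the same difference for each gene. They differ in the estimate of spread and are not independent.

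**Figure D1:**
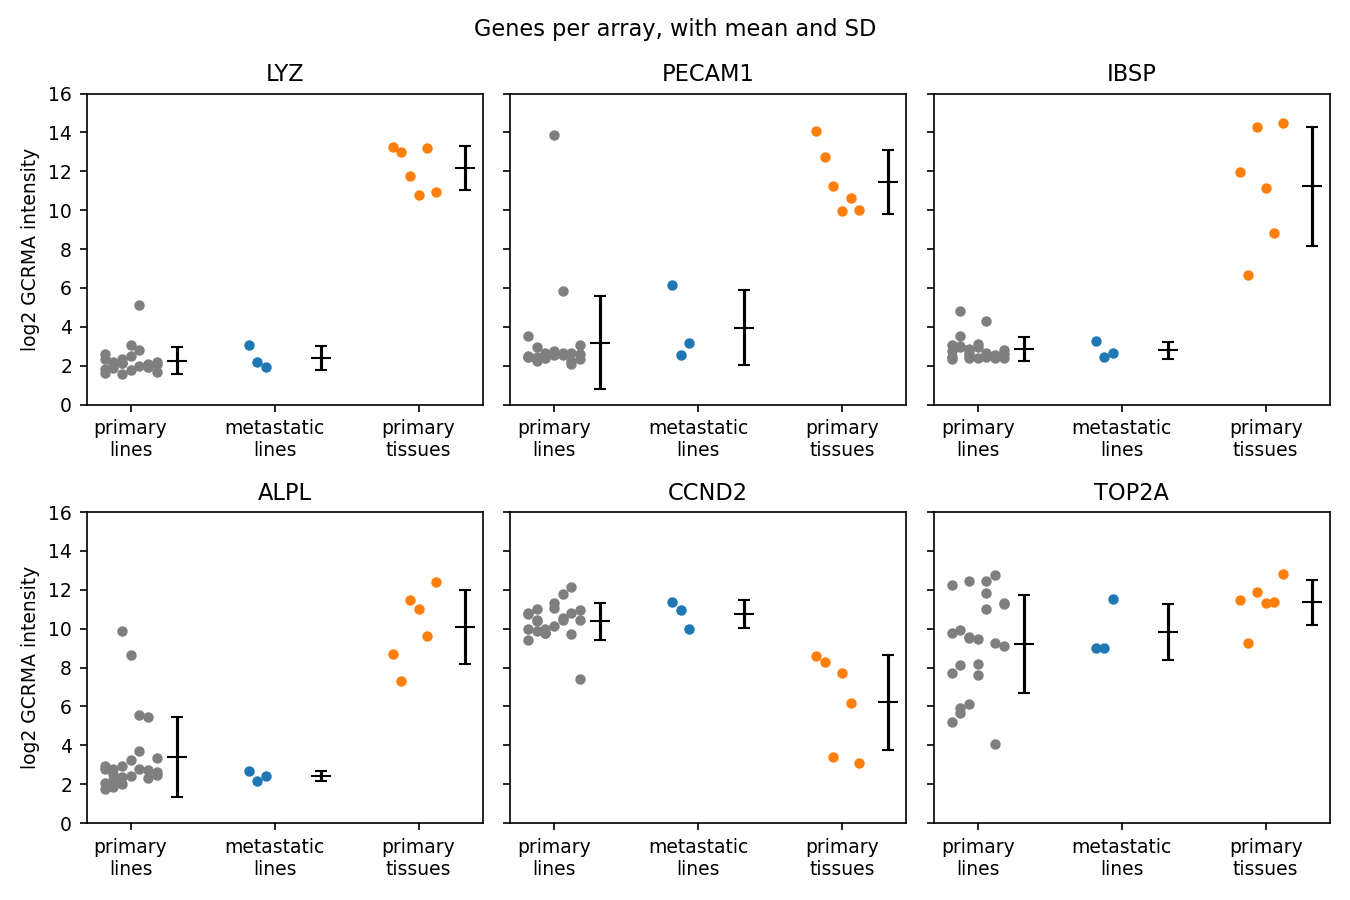
Log2 GCRMA intensity of LYZ, PECAM1, IBSP, ALPL, CCND2 and TOP2A. Each point is an array (both line arrays of dog 22 averaged) in 24 primary lines, 3 metastatic lines and 6 primary tissues, and bars give mean and SD. LYZ lies above 10 in every tissue and below 6 in every line, whereas PECAM1 reaches 13.88 in primary line 4.

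Macrophage and MHC class II genes were lower in the lines. All 14 measured monocyte and macrophage genes were lower, with a median of -5.67 (camera adjusted p = 4.8e-36), and C1QA and C1QC, which encode complement C1q chains made by macrophages, were lower by 7.65 and 7.58 log2 units. Both were near background in lines (2.24 and 2.35, 0 of 24 over log2 5), so their differences are best read as lower bounds. All 8 MHC class II genes were lower, with a median of -7.55 (adjusted p = 3.3e-12), and the invariant chain CD74 stood at 3.63 ± 1.67 in lines and 11.16 ± 1.59 in tissues. Of the B and plasma cell list only JCHAIN was measured, at -0.39 (adjusted p = 0.540). It was over log2 5 in 24 of 24 lines (9.35 ± 0.62), and another probe set gave 1.01. Its signal therefore does not compare plasma cell content. No gene of the T and NK cell or erythroid lists passed the filter on dim probe sets. In the skeletal muscle list MYH1 and ACTA1 were measured, at -0.95 (adjusted p = 0.0505) and 0.89 (adjusted p = 0.541), and MYH1 was called without tissue 2, 3 or 6.

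Part of the endothelial, osteoclast, adipocyte and osteoblast genes were called lower in lines, and the members not called were not all expressed there. Members with a median over log2 5 across the primary lines were 3 of 11 endothelial and 2 of 6 osteoclast genes. For adipocyte genes they were 0 of 6, and for osteoblast and bone matrix genes 5 of 11. The endothelial list had 9 of 11 members lower (median -3.76, adjusted p = 2.4e-09), among them PECAM1 at -8.26, KDR at -5.87 and EMCN at -5.77. In the osteoclast list 3 of 6 members were lower (MMP9, ACP5 and ATP6V0D2; median -2.24, adjusted p = 2.8e-05), while the collagenase CTSK stood at 13.02 ± 0.83 in lines and 13.28 ± 0.44 in tissues. The adipocyte list had 3 of 6 lower (CD36, LPL and PPARG; median -3.01, adjusted p = 0.00041). The osteoblast and bone matrix list had 5 of 11 lower over all genes tested, and 6 lower adjusted over the list alone (median -2.58, adjusted p = 6.6e-06). Alkaline phosphatase (ALPL, -6.69), osteopontin (SPP1, -7.38), IBSP, the parathyroid hormone receptor PTH1R (-6.21) and the transcription factor DLX5 (-2.91) were lower. Type I collagen stood at similar levels: COL1A1 was 13.66 ± 0.49 in lines and 13.84 ± 0.28 in tissues, and COL1A2 14.31 ± 0.70 and 14.65 ± 0.11. Both lie near the highest list gene value of the primary lines (COL3A1 at 14.87), and saturation of the signal was not excluded. These 6 lists, macrophage, MHC class II, osteoclast, endothelial, adipocyte and osteoblast, kept their call with an estimated correlation (adjusted p from 0.00011 to 0.025). All 6 were also called within title prefix 3 at the preset correlation, and none there with an estimated correlation (adjusted p from 0.056 to 0.253). ATP6V0D2 (-4.80) and PPARG (-4.18) lost their call there (adjusted p = 0.110 for each), and EMCN lost its own in females alone (adjusted p = 0.069). Primary line 4 stood apart within the endothelial list, with PECAM1 at 13.88 and EMCN at 13.88.

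Matrix lists differed less. In the cartilage list ACAN (-5.78) and COL2A1 (-2.82) were lower among 5 measured genes (median -0.64, adjusted p = 0.036), and the call was lost with an estimated correlation (adjusted p = 0.172). It was also lost without tissue 6 (adjusted p = 0.0501), without primary line 4 (adjusted p = 0.0588), with the filter at log2 7 (adjusted p = 0.244) and after quantile normalization (adjusted p = 0.192). COL2A1 lost its call within title prefix 3 (-3.17, adjusted p = 0.137), though its size did not fall, and was at 0.17 without the filter on dim probe sets, from another probe set. The interstitial matrix list was not called (adjusted p = 0.538, or 0.818 with an estimated correlation). Its median was 0.11, its mean -0.03 and the direction of the test up. COL14A1 differed by -3.14 (adjusted p = 0.0062), whereas POSTN (-2.75, adjusted p = 0.144) and THBS2 (1.86, adjusted p = 0.178) missed the threshold. COL14A1 was at -1.28 and lost its call within title prefix 3 (adjusted p = 0.699) and with title prefix as a covariate (adjusted p = 0.631), where POSTN was at -6.92 (adjusted p = 0.063 and 0.079) and THBS2 at -2.22. The interstitial median within title prefix 3 was -0.74 (adjusted p = 0.0094, or adjusted p = 0.413 with an estimated correlation). The pericyte and smooth muscle list went both ways, with RGS5 (-4.99) and MCAM (-4.87) lower and TAGLN (2.29) higher in lines, and was not called (median -0.37, adjusted p = 0.118), except with dog as a random block (adjusted p = 0.0063). TAGLN lost its call without tissue 3 or 6 and in females alone, and both TAGLN (adjusted p = 0.323) and MCAM (adjusted p = 0.124) lost theirs within title prefix 3 and with title prefix as a covariate.

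The hypoxia and cholesterol lists were called as higher in lines, though most of their members did not pass. In the hypoxia and glycolysis list 3 of 13 members passed over all genes (ADM, CA9 and VEGFA, at 3.83, 3.94 and 2.20), 6 did adjusted over the list alone, and the median was 0.91 (adjusted p = 3.5e-06). With an estimated correlation its adjusted p was 0.135, and within title prefix 3 the median was 0.35 with an adjusted p of 0.304. VEGFA was at 0.39 there (adjusted p = 0.818), and was not called with title prefix as a covariate (adjusted p = 0.760). In the cholesterol synthesis list 5 of 13 members were higher, or 6 adjusted over the list alone, with a median of 1.11 (adjusted p = 5.8e-06). Its largest were INSIG1 (3.55), SC5D (2.90) and DHCR7 (2.89), and its adjusted p was 0.188 with an estimated correlation. The list was called within title prefix 3 (median 1.69, adjusted p = 1.6e-05, or adjusted p = 0.253 with an estimated correlation), but INSIG1 was at 1.63 (adjusted p = 0.260) and SC5D (adjusted p = 0.081) and DHCR7 (adjusted p = 0.060) also lost their call. With title prefix as a covariate INSIG1 (adjusted p = 0.456) and DHCR7 (adjusted p = 0.210) were not called and SC5D was (adjusted p = 0.020). In dog 23, 2 of its 13 members were higher in the line. The interferon response list was lower (5 of 10 members, median -2.09, adjusted p = 0.014), led by IFI44L (-3.24), USP18 (-3.07) and MX1 (-2.91). That call was lost with an estimated correlation (adjusted p = 0.460) and without tissue 4 (adjusted p = 0.0548), and MX1 lost its own without tissue 2, 3, 4 or 5, without the filter and in both title prefix fits. USP18 lost its call with title prefix as a covariate (adjusted p = 0.128), and all 3 in females alone. Immediate early genes (2 of 10 lower: FOS at -2.41 and ZFP36 at -1.12; NR4A1 at -1.12 did not pass; list adjusted p = 0.620) and complement genes (2 of 9 lower: C3 at -4.46 and CFI at -2.43; C1R at -1.79 did not pass; list adjusted p = 0.190) were not called as lists. FOS lost its call without tissue 5, ZFP36 without tissue 2 or 5 and after quantile normalization, and CFI without tissue 2, and FOS, ZFP36, C3 and CFI lost theirs in females alone. Within title prefix 3 and with title prefix as a covariate FOS (-2.83, adjusted p = 0.191 and 0.190), ZFP36 (-1.24, adjusted p = 0.378 and 0.198) and C3 (-4.52, adjusted p = 0.2496 and 0.190) lost their call without a smaller difference. C1R was at -5.28 there and called (adjusted p = 0.021 and 0.048). CFI was called with the covariate (adjusted p = 0.040) and not within title prefix 3 (adjusted p = 0.119). The complement median was -3.49 there and was called (adjusted p = 0.00014, or adjusted p = 0.253 with an estimated correlation).

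Proliferation lists missed the threshold over all arrays and turned direction within title prefix 3, which held 2 lines. The G2/M list had a median of -1.34 (0 of 21 called, adjusted p = 0.053), the G1/S and replication list -0.78 (1 of 21, CCNE2, called; adjusted p = 0.115) and the DNA damage checkpoint and repair list -0.59 (2 of 11, BRCA2 and CHEK2, lower; adjusted p = 0.118). CCNE2 lost its call with dog as a random block (-1.95, adjusted p = 0.0743), with both line arrays of dog 22 kept apart (adjusted p = 0.0668) and without tissue 1, 3, 4 or 6, CHEK2 without tissue 3, 4, 5 or 6, and both of them and BRCA2 in females alone (adjusted p = 0.082, 0.063 and 0.055). Adjusted over the list alone, 0 G1/S genes and 2 DNA damage genes passed. The topoisomerase TOP2A was 9.19 ± 2.52 in lines and 11.36 ± 1.16 in tissues (adjusted p = 0.117), AURKB differed by -1.98 (adjusted p = 0.101, or 0.018 with array weights) and ORC1 by -2.09 (adjusted p = 0.158). Within title prefix 3 the medians were 1.70, 1.46 and 1.56, each called as higher in lines at the preset correlation (adjusted p = 2.4e-05, 1.3e-05 and 0.0029), but not there with an estimated correlation (adjusted p = 0.413, 0.378 and 0.378). Those values rest on primary lines 22 and 23. The G2/M scores of dog 22 (1.31, both line arrays averaged) and primary line 23 (1.35) were the highest of the primary lines. The turn can therefore follow from which lines carried that prefix. Over all arrays and at the preset correlation the G2/M list lay close to the threshold, and with an estimated correlation the adjusted p was 0.703 for G2/M, 0.717 for G1/S and 0.647 for DNA damage. At the preset correlation G2/M was called as lower in lines without the filter (adjusted p = 0.018), with the filter at log2 7 (0.043), after quantile normalization (0.045), with the probe set of largest interquartile range (0.046) and without tissue 2 (median -1.88, adjusted p = 0.010). The G1/S list was called without the filter (adjusted p = 0.026) or tissue 2 (0.017), and the DNA damage list with the filter at log2 7 (0.033) or without tissue 2 (0.042).

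Of 19 measured osteosarcoma genes, 2 were higher in lines and 6 lower, and the list was not called (median -0.36, adjusted p = 0.258). The receptor MET (1.82, SE 0.50, adjusted p = 0.0084) and VEGFA (2.20, SE 0.38, but 0.39 within title prefix 3) were higher. The Wnt inhibitor WIF1 (-6.00, SE 1.09), KIT (-2.98), TWIST1 (-2.85), IGF1 (-2.60), KDR and FOS were lower, and IGF1 lost its call without tissue 1. In title prefix 3 alone WIF1 (-5.76, adjusted p = 0.100), KIT (-2.92, adjusted p = 0.229), TWIST1 (-2.20, adjusted p = 0.177), IGF1 (-3.08, adjusted p = 0.422) and FOS lost their call there, and of these only KIT was called with title prefix as a covariate (adjusted p = 0.0065). MET lost its call with the covariate (2.57, adjusted p = 0.0501) and in females alone (adjusted p = 0.121), and so did IGF1 (adjusted p = 0.238) and FOS in females. MDM2 was higher by 1.61-fold (adjusted p = 0.0029), below the 2-fold minimum. MYC (-0.43, adjusted p = 0.469), CDK4 (-0.36, adjusted p = 0.413), RUNX2 (-0.35, adjusted p = 0.492), EZR (0.04, adjusted p = 0.901) and ERBB2 (0.42, adjusted p = 0.263) missed the threshold. Both title prefix fits rest on the same 2 lines and give the same differences. There ERBB2 was at 1.94 and called (adjusted p = 0.035 within title prefix 3 and 0.0033 with the covariate), and MYC (0.67) and CDK4 (0.60) turned direction without a call. ERBB2 and RUNX2 were dim in both groups, so their differences are uncertain. ERBB2 was at 4.35 in lines (3 of 24 over log2 5) and 3.93 in tissues (0 of 6). RUNX2 was at 4.24 in lines (5 of 24) and 4.59 in tissues (1 of 6).

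**Figure D2:**
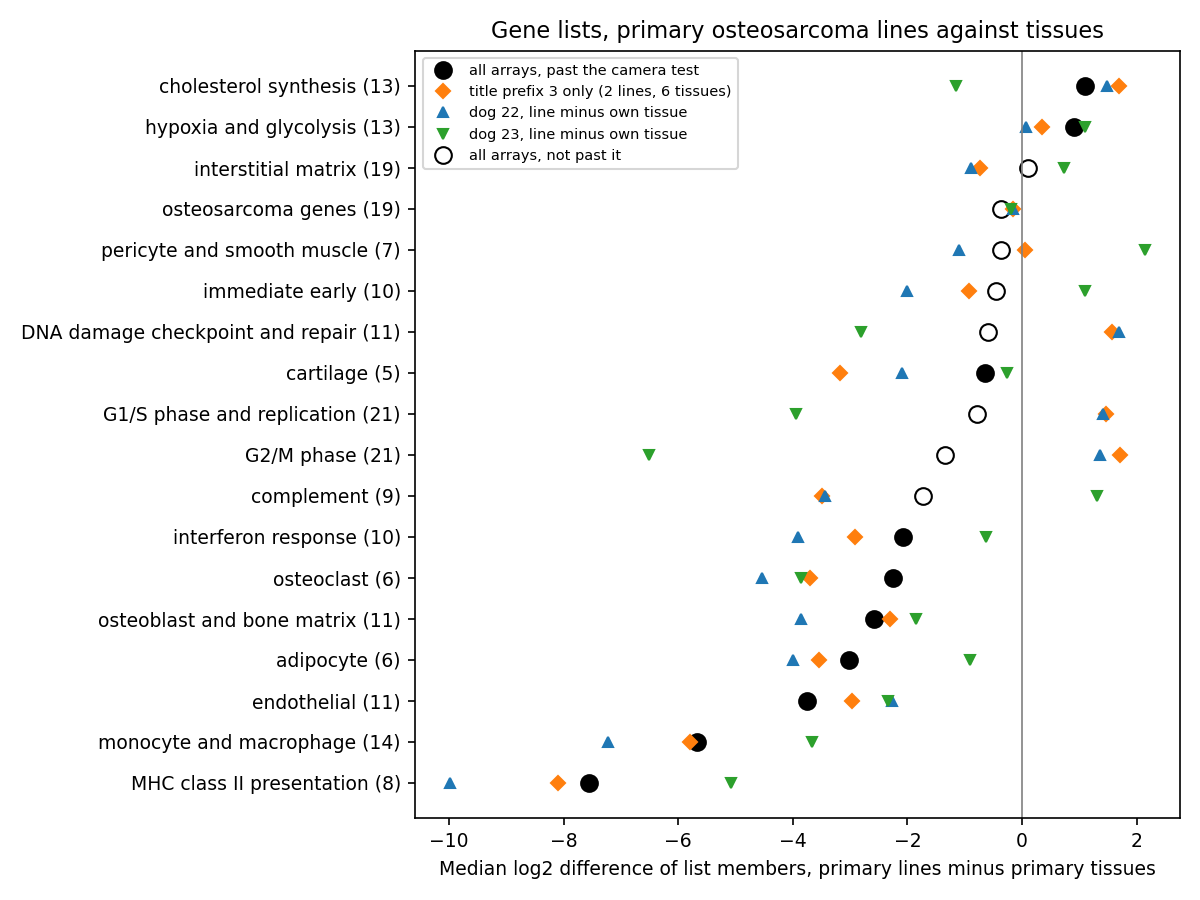
Median log2 difference of list members, primary lines minus primary tissues, with the number of measured members beside each list. Filled circles passed the camera test over all arrays and open circles did not; triangles give dogs 22 and 23, and diamonds title prefix 3. The G2/M median is -1.34 over all arrays, 1.36 in dog 22, -6.52 in dog 23 and 1.70 in title prefix 3.

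Dogs 22 and 23 gave both a line and a tissue. Of the 1148 called genes, 879 (76.6%, Wilson 95% interval 74.0% to 78.9%) differed in the called direction in both dogs. Both dogs took part in those calls, which raises that share by construction. Of 879 genes called in the other dogs alone (22 lines, 4 tissues), 605 (68.8%, Wilson 95% interval 65.7% to 71.8%) had the same direction in both dogs, against 36.0% of all 7849 genes, a comparison added after the first. The intervals cover counting error only, and genes are not independent. All 14 macrophage genes were lower in the line of either dog, with medians of -7.23 and -3.67, and IBSP, named by a rule that required the same direction in both dogs, was lower by 6.17 and 12.06 log2 units. Proliferation genes opposed each other: 21 of 21 G2/M genes were higher in the line than in the tissue of dog 22 and 0 of 21 in dog 23. TOP2A differed by 1.08 in dog 22 and by -8.75 in dog 23. The line of dog 23 had the lowest G2/M score of the primary lines (-1.62), and that of dog 22 had a score of 1.31. With 2 dogs no test was made.

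Few genes passed the test between lines from metastases and primary lines. The semaphorin and VEGF co-receptor neuropilin NRP1 was higher at 7.10 ± 1.64 (SD, n = 3) against 4.09 ± 0.68 (n = 24), an 8.05-fold difference (SE 0.50 on the log2 scale). Only 2 of 24 primary lines were over log2 5, so this fold is set against a level near background and is not exact. The transcription factor MEIS1 stood at 6.06 ± 2.67 against 3.13 ± 0.91, and OCA2, a melanosome transporter, at 7.37 ± 1.53 against 3.91 ± 1.23. NRP1 was the 1 gene called by limma (adjusted p = 0.0074), MEIS1 and OCA2 had an adjusted p of 0.188, and 534 genes had an unadjusted p under 0.05. NRP1 was at 8.61, 5.35 and 7.34 in metastatic lines 1, 2 and 3. Another NRP1 probe set, with the largest interquartile range, gave 0.79 (adjusted p = 0.771). Without metastatic line 1 the NRP1 difference was 2.25 (adjusted p = 0.927), without line 3 it was 2.89 (adjusted p = 0.112), and without line 2 it was 3.89, where 24 genes were called, MEIS1 (adjusted p = 0.00015) and OCA2 (adjusted p = 0.048) among them. MEIS1 was also called with array weights (adjusted p = 0.021), and NRP1 was not in Rottweiler lines alone (2.21, adjusted p = 1.0). Metastatic line 1 had a GAPDH 3′ minus 5′ difference of 5.92, above the primary lines (2.46 to 4.17) and metastatic lines 2 and 3 (3.12 and 3.21), and the lowest percentage of probe sets over log2 5 (32.0), so its RNA quality stays open.

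At the preset correlation 4 lists were called in metastatic lines, MHC class II as higher and hypoxia, cartilage and osteoblast as lower. However, 67 of 100 splits of the lines called as many lists, so chance cannot be excluded for that number. The MHC class II median was 1.56 (8 genes, camera adjusted p = 0.0019, or adjusted p = 0.457 with an estimated correlation). Without metastatic line 1, the line with the high GAPDH difference (5.92), it turned to -0.28, and that line had DLA-DRA at 9.54 against a median of 2.12 over the lines. The same line had KRT18 at 13.51 (line median 2.62) and EPCAM at 11.34 (line median 2.43), genes picked after their values were seen. The hypoxia and glycolysis median was -0.81 (13 genes, adjusted p = 3.7e-05, or adjusted p = 0.380 with an estimated correlation). For cartilage the median was -1.84 (5 genes, adjusted p = 0.0041, or adjusted p = 0.210 with an estimated correlation), and for osteoblast and bone matrix -0.15 (11 genes, adjusted p = 0.042, or adjusted p = 0.458 with an estimated correlation). No member of these 4 lists passed over all genes tested, and adjusted over the list alone 1 cartilage gene was lower. The osteoblast call was lost without metastatic line 2 (adjusted p = 0.0607) or line 3 (0.324), after quantile normalization (0.0716), with the probe set of largest interquartile range (0.146) and without the filter (0.379). The cartilage call was lost without line 3 (adjusted p = 0.114) and without the filter, where its median was -0.06 (adjusted p = 0.279). The other 14 lists were not called, though complement, cholesterol synthesis and interstitial matrix each gained a call in 1 of 9 alternatives. The G2/M list had a median of 0.28 and a mean of 0.16 with the test pointing down (adjusted p = 0.970), and the G1/S list a median of -0.07 and a mean of 0.03 with the test pointing down.

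Among 11 primary lines from dogs labelled SOC, survival labels ran from 4.04 to 64.01, each treated as a full survival time. No gene passed the test for survival in limma (0 called, 383 with an unadjusted p under 0.05). The genes with the smallest p were NMS, a neuropeptide, at 0.73 per doubling of survival (SE 0.10, adjusted p = 0.129), GAREM1 at -0.69 (SE 0.11, adjusted p = 0.182) and TRIM3 at 0.45 (SE 0.07, adjusted p = 0.182). All were dim, with means of 3.93, 4.60 and 4.78 and with 1, 3 and 3 of 11 lines over log2 5. Proliferation lists were lower with longer survival in camera: G2/M (median -0.75 per doubling, adjusted p = 6.1e-11), G1/S (-0.34, adjusted p = 7.2e-06) and DNA damage (-0.24, adjusted p = 0.022), and complement was higher (0.29, adjusted p = 0.024). All 4 calls were lost (adjusted p = 0.80 for each with an estimated correlation). DNA damage also lost its call with the filter at log2 7 (adjusted p = 0.397), complement without the filter (adjusted p = 0.156), and both with interrupted SOC included (adjusted p = 0.071). The G2/M score itself gave Pearson r = -0.525 (permutation p = 0.096) and Spearman rho = -0.48 (permutation p = 0.14) over the 11 lines, 1 of 18 list scores related to survival, with an adjusted p of 0.79. Without the 2 dogs farthest from the median survival r was -0.36, and within title prefix 2 (n = 9) it was -0.42, so no relation was shown. For the other 14 lists the adjusted camera p was 0.058 or more. Of these, cholesterol synthesis was called in 4 of 7 alternatives. Hypoxia, interferon and interstitial matrix were called in 2 each, and MHC class II and pericyte in 1 each. MHC class II genes had a median of -0.06 and a mean of 0.01 with the test pointing down, and adipocyte genes a median of -0.03 and a mean of 0.09 with the test pointing up.

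No gene passed the test between male and female lines. In simulation this test recovered 52.2% of changes of 1 on the log2 scale. Many genes were changed at once there, which eases the adjusted threshold, so that share is too high where few genes differ. In 13 male and 10 female primary lines limma called 0 genes, and 319 had an unadjusted p under 0.05. With the probe set of largest interquartile range 1 gene was called. The metallothionein MT2A (-1.35, male minus female), ULK4 (1.08) and RNF113A (-0.59) had the smallest p, each with an adjusted p of 1.0. X-linked KDM6A, which escapes X inactivation in many mammals, stood at 5.18 ± 0.98 in males and 6.52 ± 1.20 in females (unadjusted limma p = 0.0053, adjusted p = 1.0). DDX3X differed by -0.27 and EIF1AX by -0.39. Y-linked genes were not analysed here, so sex labels were not checked through them.

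Between 10 Rottweiler and 7 Golden Retriever lines the signal of 2 genes differed, and 850 had an unadjusted limma p under 0.05. MFAP3, a microfibril-associated glycoprotein, was lower in Rottweiler lines (3.13 ± 0.57 SD against 7.24 ± 2.02, difference -4.31, SE 0.65, adjusted p = 0.018). ZBED1, a zinc-finger protein, was higher (5.42 ± 0.44 against 3.11 ± 0.89, difference 2.24, SE 0.33, adjusted p = 0.018). PUS1, a pseudouridine synthase, was 2.84-fold apart and missed the threshold (adjusted p = 0.144), but was called without sex in the fit (adjusted p = 0.048) and with metastatic lines (adjusted p = 0.025). The second MFAP3 probe set, at 2.06 ± 0.56 and 5.16 ± 2.03, and the second ZBED1 probe set, at 4.97 ± 0.53 and 3.53 ± 0.46, differed in the same direction. Without the filter on dim probe sets neither gene was called (adjusted p = 0.053) at the same differences. After quantile normalization ZBED1 was not (2.17, adjusted p = 0.0564), and within title prefix 2 neither was, with differences of -4.49 for MFAP3 and 2.52 for ZBED1 (adjusted p = 0.102). Breed variants in the probe sequences were not analysed here, so these are differences in probe signal that need not be differences in expression.

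**Figure D3:**
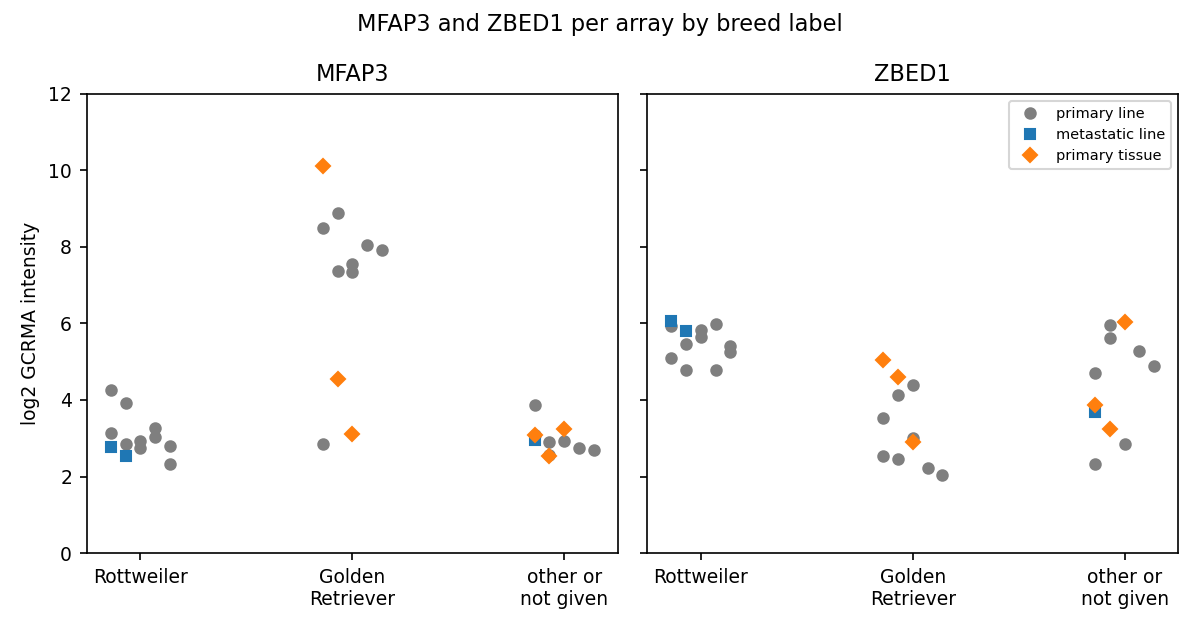
Log2 GCRMA intensity of MFAP3 and ZBED1 in each of the 34 arrays by breed label. MFAP3 is above 7 in 8 of 11 Golden Retriever arrays and in 0 of 23 others, whose highest value is 4.27.

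Primary lines differed widely from each other in proliferation genes. The G2/M score ranged from -1.62 in primary line 20 to 1.35 in primary line 23, and the median member of the list spanned 7.22 log2 units across the 24 lines, against 8.54 in the complement, 8.36 in the interferon, 7.45 in the adipocyte and 7.07 in the pericyte list. TOP2A ran from 4.05 to 12.77 and CCNB2, a mitotic cyclin, from 2.86 to 11.32. Of 17 relations to other list scores, 9 had an adjusted permutation p under 0.05. The G2/M score rose with the G1/S score (r = 0.979, rho = 0.973, adjusted p = 8.5e-05, the smallest these draws allow) and the DNA damage score (r = 0.896, rho = 0.917, adjusted p = 8.5e-05). It also rose with the cholesterol (r = 0.556, adjusted p = 0.013, rho = 0.461, adjusted p = 0.061) and interferon scores (r = 0.461, adjusted p = 0.036, rho = 0.443, adjusted p = 0.066). It fell as pericyte and smooth muscle genes (r = -0.649, adjusted p = 0.0023, rho = -0.724), interstitial matrix (r = -0.586, adjusted p = 0.0051, rho = -0.725), hypoxia (r = -0.651, adjusted p = 0.0023, rho = -0.580) and complement (r = -0.663, adjusted p = 0.0022, rho = -0.755) rose. The cartilage relation (r = -0.460, adjusted p = 0.043, rho = -0.357, adjusted p = 0.166) was the weakest of those past the threshold. Without the 2 lines farthest from the median score r stayed at 0.981, -0.587, -0.560, -0.650 and -0.558 for G1/S, pericyte, interstitial, hypoxia and complement, and was weaker at 0.40 for cholesterol and -0.318 for cartilage. Within title prefix 2 (n = 19) r was 0.980, -0.775, -0.837, -0.671 and -0.720 for the same 5 lists (permutation p from 5e-05, the smallest possible with the 20000 draws used there, to 0.0016).

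**Figure D4:**
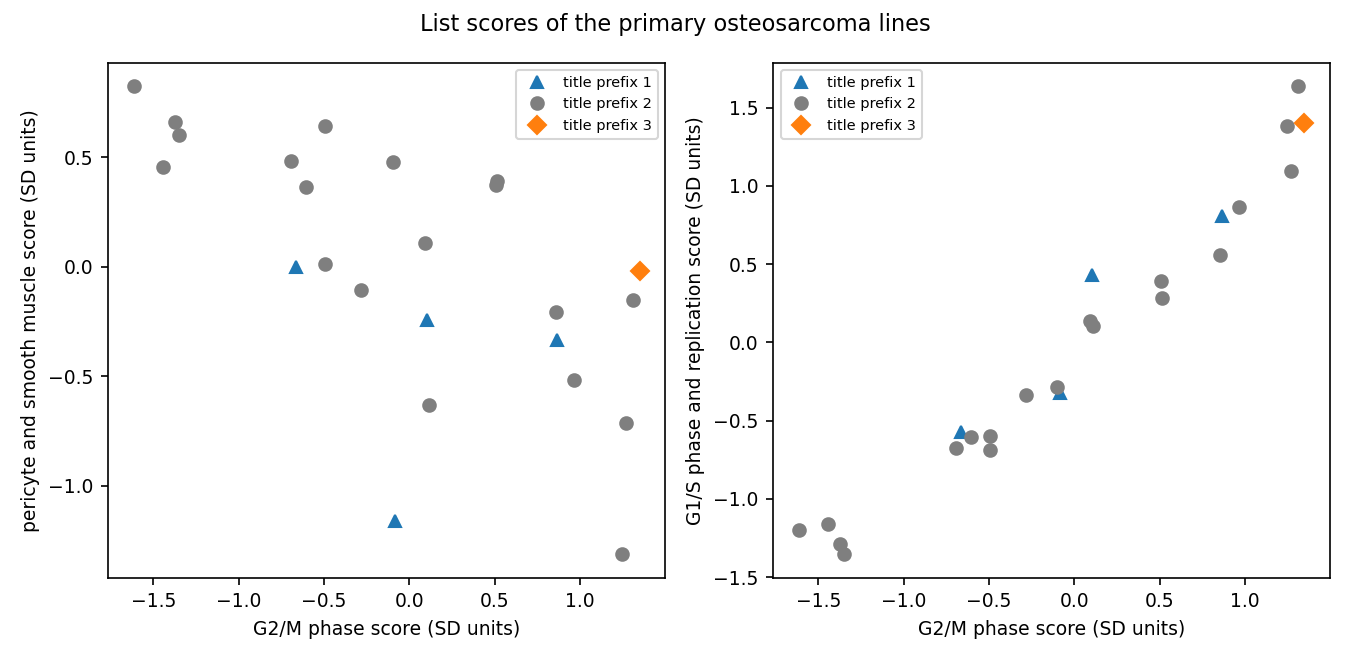
G2/M phase score against the pericyte and smooth muscle score (left) and the G1/S phase and replication score (right) of 24 primary lines, in units of SD across the lines, with symbols for the title prefix. The averaged arrays of dog 22 carry the symbol of title prefix 2. The score falls with pericyte genes (r = -0.649) and rises with G1/S genes (r = 0.979).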

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

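Every test of primary line 4 and of the spread of the G2/M score given here was chosen only after the result was seen, and so were the splits for lists with an estimated correlation, whereas the other splits of the samples were planned before.

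In 47 tests of gaps between samples of a group, 2 samples lay far from the rest, and about 5% would by chance. ABCA8 was at 6.76 in tissue 2 and between 2.39 and 3.94 in the other tissues. MFAP3 was at 2.85 in primary line 20, a Golden Retriever line, and between 7.33 and 8.89 in the other lines of that breed. The same dog's tissue was also low, at 3.11, whereas in dog 22, of the same breed, the line arrays were at 7.90 and 7.55 and the tissue at 4.54.

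In dogs 22 and 23, line minus tissue went opposite ways in 5 lists by a required share of members that was set after the values were seen, a difference that was not tested. Dog 22 minus dog 23 was 7.88 for G2/M, 5.35 for G1/S, 2.64 for cholesterol synthesis, -3.11 for immediate early and -4.76 for complement genes. The DNA damage list, with 8 of 11 members higher in the line of dog 22 and 0 of 11 in that of dog 23 (medians 1.69 and -2.81), fell short of that share.

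Some genes high in few tissues were left out by the filter on dim probe sets. In tissue 5, 8 T and NK cell genes were over log2 5 and over every line, among them CD3D at 8.81, NKG7 at 7.61 and GZMK at 7.09. In tissue 4, 3 skeletal muscle genes were: MYL1 at 7.01, MYLPF at 6.37 (5.90 in tissue 5), and MYH1, which passed the filter, at 5.18 (6.02 in tissue 5) against 5.16 in the highest line. TNNI2 was at 9.82 in tissue 6 against 2.85 in the highest line.

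Of 100 splits of the lines and tissues into groups of the same sizes, 1, the real one, gave as many as 1148 called genes, and the highest of the others gave 10, so chance can be excluded. For the 10 lists called with a preset correlation, 13 of 100 splits gave as many and the highest other gave 15, so chance cannot be excluded for that number. For the 6 lists called with an estimated correlation, 1 split gave as many and the highest other gave 1, so chance can be excluded for that number. For the 1 gene called in metastatic lines, 28 of 100 splits gave as many and the highest other gave 542, so chance cannot be excluded, and a number that far above the real one points to a structure among the lines, which was not tested. For the 4 lists called there, 67 splits gave as many and the highest other gave 14, so chance cannot be excluded. For sex, 100 of 100 splits gave at least the real 0 genes and the highest gave 1. For breed, 1 split gave the real 2 genes and the highest other gave 1.

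Primary line 4 had 9 of 11 endothelial genes above every other primary line, with PECAM1 and EMCN at 13.88 and KDR at 10.81, although VWF (3.02) and CD34 (2.96) were not above them, and TIE1 (2.31 against 2.30 in the next line) is near background and below its tissue mean of 5.96. Poor RNA is argued against, as 0 of its 2 differences between 3′ and 5′ probe sets lay outside the other lines. A mixture with at least 10% of cells like the other lines is argued against, since 2 of 8 matrix genes that are high in those lines lay more than 10-fold below their lowest, the farthest at 5.36% of it, which leaves a smaller share open. For blood or marrow cells, 10 of 14 macrophage genes were at or below the highest of the other lines, which argues against macrophages. However, LAPTM5 (13.74), CD14 (7.99) and CD68 (8.70) were above the other lines. So were 4 of 6 osteoclast genes, among them ACP5 (7.68 against at most 5.52) and TCIRG1 (10.17 against at most 8.81), whereas MMP9 and CTSK were not. Other marrow cells thus stay open. A candidate explanation that stays open is a culture of endothelial-like cells, tumour or not, and no biological explanation was tested; 1 of the 11 endothelial genes is on another list and 3 are over log2 5 in the median line.

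The G2/M score of the primary lines ranged from -1.62 to 1.35. RNA quality stays open: between the score and the actin 3′ minus 5′ difference r was -0.338 (permutation p = 0.10, adjusted p = 0.20), with a 95% interval from -0.652 to 0.0757 that leaves a sizeable relation possible, and the rule for this test was changed after its value was seen. Title prefix cannot give the spread among lines that share a prefix. Within title prefix 2 the SD of the score was 1.04 times that over all lines. Primary lines 20 and 25, both of that prefix, stood at -1.62 and 1.27. As title prefix 2 held 19 of the primary lines, both SDs rest largely on the same lines. Their ratio therefore cannot exclude a shift between prefixes, and primary line 23, of title prefix 3, had the highest score (1.35). The relation to the pericyte and smooth muscle score (r = -0.649) would suit, as a hypothesis, non-tumour mesenchymal cells in the slower lines. This list had been seen to vary with the score before the test, 1 of its 7 genes is on another list and 5 are over log2 5 in the median line, so a different state of the tumour cells may give the same relation.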

How the results depend on the processing

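Leaving out primary line 4, making calls without dogs 22 and 23, and an estimated correlation within title prefix 3 were chosen only after the data were seen, and the others were planned.

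Primary lines against tissues gave 1148 genes, 845 with the filter at log2 7 and 1474 with array weights. Testing all probe sets gave 2949, no fold minimum 1774, females 707, title prefix as a covariate 493 and title prefix 3 alone 251. Leaving out a tissue gave 987 to 1178, and leaving out primary line 4 gave 1207. With dog as a replicate block, which uses the pairing of dogs 22 and 23, 1079 genes were called. The block also called the pericyte list (adjusted p = 0.0063) and ended no list call, but CCNE2 lost its own (-1.95, adjusted p = 0.0743). Lists called went from 10 to 6 with an estimated correlation, and to 0 with an estimated correlation within title prefix 3, a fit of 8 arrays. In dog 22's title prefix 3 array, 71.9% of called genes kept their direction in both dogs against 76.6%, and of genes called without dogs 22 and 23, 68.8% did; those dogs then have no part in the calls.

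In lines against tissues, values that reversed with a call before or after were COL2A1 without the filter (0.17, from another probe set of the gene), and, both with title prefix as a covariate and in title prefix 3 alone, CCNE2 (1.46), BRCA2 (1.20), CHEK2 (0.47), and the G2/M (1.70), G1/S (1.46) and DNA damage (1.56) lists. Interstitial matrix also reversed, to -0.74, in title prefix 3 alone. In the same fits 10 uncalled genes turned sign, among them TOP2A (1.20), AURKB (1.74), ORC1 (1.85) and THBS2 (-2.22). These 2 fits rest on fewer lines, and otherwise the cause was not tested.

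Metastatic lines gave 1 gene and 0 with the filter at log2 7, with the probe set of largest interquartile range or in Rottweilers alone, 4 with array weights, and 0 to 24 with each line left out. Their 4 lists became 2 without the filter and 0 with an estimated correlation, and MHC class II ran from -0.28 without metastatic line 1 to 2.78 without metastatic line 3. For survival, lists went from 4 to 10 with every line and to 0 with an estimated correlation, and the G2/M score gave r from -0.321 with every line (permutation p = 0.15) and -0.457 with interrupted SOC (0.10) to -0.578 with the metastatic SOC line (0.047). The slope of the G2/M list was -0.25 with every line. Sex gave 1 gene with the probe set of largest interquartile range. Breed gave 0 without the filter, 1 with the filter at log2 7, 1 after quantile normalization, 1 in title prefix 2 and 5 with metastatic lines. With first principal components, G2/M against adipocyte turned to -0.47 and 11 relations passed in place of 9. The cause was not tested.

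Over the named genes 1741 further values stayed called or uncalled, 32 of them with the sign turned, 95 lost the call, 17 gained it and 7 reversed with a call before or after. For lists the numbers were 501, 34, 40, 27 and 8. Of the 20 named genes of lines against tissues, 11 kept their call throughout, 8 lost it in title prefix 3, 6 with title prefix as a covariate and 1 in females. Quantile normalization moved the median of all genes by -0.01.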

Other observations

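All tests here but that of genes silent in 1 line were chosen only after the result was seen, and so were the genes named from single lines.

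Single lines stood apart in genes that the comparisons leave out, and no list or test was fixed for them. Primary line 12 had the highest interferon genes of the lines, with ISG15 at 13.99 against a median of 3.83 and MX1 at 12.87 against 3.57. Metastatic line 1 had KRT18 at 13.51 (line median 2.62), EPCAM at 11.34 (median 2.43, and 12.19 in another line), C3 at 13.50 (median 2.52) and THY1 at 2.88 (median 9.55). Primary line 7 and metastatic line 3, its nearest array (r = 0.967), were both low in PRRX1 (2.78 and 6.20, median 11.64), CDH11 (3.07 and 6.79, median 13.12) and COL6A3 (2.17 and 3.80, median 10.82), and above the line median in KRT18 (9.03 and 7.02). Primary line 4 had the cytokines IL6 at 13.47 (median 2.97) and CXCL8 at 13.19 (median 2.63), and the matrix genes DCN at 5.16 (median 13.63) and MMP2 at 3.54 (median 12.38).

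Across the 24 primary lines the G2/M score fell as the p53 targets CDKN1A (r = -0.706, rho = -0.618, permutation p = 1e-04) and MDM2 (r = -0.596, rho = -0.570, permutation p = 0.0018) rose, and rose with the nuclear lamin LMNB1 (r = 0.653, rho = 0.659, permutation p = 0.00054). Adjusted over these 3 the p were 3e-04, 0.0018 and 0.00081. Without the 2 lines farthest from the median, r was -0.72, -0.57 and 0.63, and within title prefix 2 it was -0.712, -0.658 and 0.607.

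Primary lines 6 and 23 shared a run of genes near background that neighbour each other on chromosome 21 of UU_Cfam_GSD_1.0: TMEM135, PRSS23, ME3, HIKESHI, EED and PICALM, at 1.35 to 1.83 in line 6 and 0.98 to 2.16 in line 23, against line medians from 7.58 to 11.36. Genes silent in exactly 1 line and over log2 6 in the others gave 1 neighbouring pair, which 421 of 10000 shuffles of gene order reached (highest 2), so random placement was not excluded. The definition was then widened to genes under log2 4 in 1 to 3 line arrays with a line median of at least 7. By it 18 pairs lay beside each other against at most 8 in 10000 shuffles. Primary line 6 held 7 of these pairs and primary line 23 held 6, most of them in the run named above. As the definition was chosen after the result was seen, this count gives no independent evidence against random placement. Shuffles also take no account of related genes that lie together, such as STEAP1 and STEAP2. Poor RNA is argued against, as 0 of 4 values of the 3′ and 5′ differences in lines 6 and 23 lay outside the other lines. A single culture under both labels cannot be told apart from separate ones. Between the arrays 18 genes were silent in 1 and high in the other, against 13 between the line arrays of dog 22. The median pair of line arrays had 35 and the lowest pair 0, so this measure cannot identify a shared culture. Lines 6 and 23 were each other's nearest array (r = 0.916), and the limits of this test were changed after its value was seen. A DNA loss shared by both lines may be a candidate explanation, and no DNA was analysed here.

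MTAP, a gene of the methionine salvage pathway, was at 1.84, 1.68, 1.72 and 1.55 in primary lines 12, 19, 22 and 23, of which lines 19 and 22 come from 1 dog, and at 3.88 in tissue 4, against a line median of 10.13.

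The test of macrophage genes in primary line 4 was reworded after its value was seen, as were the share of members required for dogs 22 and 23 and the rule of 3 genes for lists below the filter.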
